A study of Drosophila melanogaster with 24 samples.

How the data were processed

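MicroRNAs were measured by small RNA sequencing in hemolymph, the circulating fluid of the fly, and in body tissue of Drosophila melanogaster labelled male, at 2 days (young) and 25 days (old) of age. The labels put 24 libraries in 4 groups: young body (n = 4), old body (n = 8), young hemolymph (n = 4) and old hemolymph (n = 8). Per the labels' protocols, RNA came from a serum and plasma kit for hemolymph and from the standard miRNeasy kit for body tissue, so the extraction kit and the compartment cannot be told apart. Libraries were made with TruSeq small RNA reagents and sequenced as 50 base single reads. The old libraries numbered 5 to 8 carry a description code with the letter R where numbers 1 to 4 carry O, and no label says what the letters mean. The old groups were therefore kept whole and the code series were compared as a check. Nothing in the labels says whether a library came from separate flies or a separate pool, so p-values measure the spread between these libraries, which may be partly technical.

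The deposited table held 476 rows, each a mature microRNA paired with its hairpin, with a count column and a RPM column for every library. The submitters' processing notes name Bowtie 1.0, edgeR without a version, and the dm6 genome. The microRNA annotation release, the trimming and the treatment of reads with several matches are not given in the sources used here. The deposited counts were whole numbers with no normalization. The deposited RPM values equalled each count scaled to its column total, to within 0.005, and only the counts were tested. Of mature microRNAs listed under several hairpins the row with the highest total was kept, which left out 10 rows and gave 466 mature names, 329 of them with at least 1 count. Counts of miR-276a-5p and miR-276b-5p were equal in all 24 libraries, so reads shared by near-identical family members may be assigned to several names, and values for members of the miR-2, miR-276, miR-281 and miR-310 families are uncertain to that extent.

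Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were filtered with filterByExpr at its minimum count of 10, libraries were scaled with TMM factors, and the quasi-likelihood F test was used with Benjamini-Hochberg adjustment at 0.05. The comparisons of compartments and the difference of age changes (hemolymph minus body) were fitted over all 24 libraries, and the comparisons of ages within the 12 libraries of a compartment. A standard error is the absolute log2 fold change divided by the square root of F. Levels are CPM of all microRNA counts, as mean ± SD. TMM scaling sets changes relative to the bulk of the microRNAs, so a change in the total amount of microRNA per volume of hemolymph or per body is not measured. Lists of microRNAs were tested with camera in limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry. Composition measures and list shares were compared with exact permutation tests of the difference in means (two-sided, scipy 1.17.1 in Python 3.11.15), adjusted over 20 composition tests and over 40 list tests. The smallest p such a test can give is 0.0286 for 4 against 4 libraries, 0.00404 for 4 against 8 and 0.000155 for 8 against 8. Numbers of microRNAs detected were compared after thinning every library to 52792 counts, the size of the shallowest, as the mean of 20 draws. As no molecular identifiers were used, counting error is a lower limit for the error of single values.

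The lists, the groups, the tests and most alternatives were fixed before the data were examined. The microRNAs named for each comparison were, by a fixed rule, the 8 largest rises and 8 largest falls with adjusted p below 0.05 and a mean of at least 100 CPM, the 10 most abundant microRNAs of each compartment, and up to 4 members of each list with the highest CPM. Further list members are named to fill in the account of a list, and were chosen after their values were seen. The alternatives covered RLE and upper-quartile factors, library size alone, no low-count filter, a mean of at least 100 CPM, summed or separate rows per mature name, DESeq2 1.42.0, limma with sample weights, robust dispersion, the replicate block, the code series singly, narrower or wider fits, and leaving out each library. Leaving out pairs of young libraries, and leaving out ovary and miR-310 family microRNAs, were chosen after seeing the data.

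Replicate numbers were checked for pairing through the correlation, across microRNAs, of deviations from the group mean. In the young groups all 4 same-numbered body and hemolymph libraries had an r above 0.1 (0.12 to 0.603), and 3 of 4 correlated best with their own number. Young body library 3 correlated better with another young hemolymph library (0.55 against 0.294). On this limited evidence those numbers were taken to pair the young samples. The main tests left the pairing out, and the replicate block, an alternative, paired the old libraries by number as well. All pairs of libraries within a group differed by more than sampling noise, and the smallest chi-square per degree of freedom was 3.94. Young libraries differed more, at 33.4 to 491 in body against 3.94 to 30.0 in old body, and 26.9 to 285 in hemolymph against 9.07 to 127. As 1 dispersion per microRNA was fitted over both ages, p-values that involve the young groups may be too small. Positions were taken from the Ensembl release 115 annotation (build BDGP6.54), in which 69 of 73 named microRNAs were matched by hairpin name, and positions of the others are not analysed here. The scripts were tested on simulated counts with the real library sizes. Each microRNA had 1 mean and 1 dispersion over the fitted libraries, the same in every group. In each of 10 simulated sets 48 microRNAs were changed. The rates below therefore do not cover the large differences between the real groups or the wider spread of the young libraries. For young hemolymph against young body (121 microRNAs) 95.9% of changes of 2 log2 units and 48.0% of changes of 1 unit were recovered, and 1.11% of unchanged microRNAs were called. For the difference of age changes (122 microRNAs) the shares were 74.7%, 30.9% and 1.52%. Recovery of 2 log2 units, of 1 unit, and the share of unchanged microRNAs called were 96.4%, 70.8% and 3.03% for the old compartments (121 microRNAs). They were 96.3%, 77.4% and 1.66% for age in body (115), and 92.8%, 55.6% and 3.23% for age in hemolymph (85). For the R and O codes they were 93.4%, 66.7% and 1.51% in body (115), and 87.3%, 41.4% and 1.06% in hemolymph (86). A raised list of 8 was found by camera in 9 of 10 sets for each compartment contrast, in 10 for each age contrast and the difference, and in 9 and 5 for the codes in body and hemolymph. Floors for microRNAs with no count cover counting error only.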

Results

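Small RNA libraries of hemolymph and of body tissue from young (2 days) and old (25 days) flies were compared to learn which microRNAs circulate, how the circulating set differs from that of the tissues, and whether the relation between them shifts with age. The total microRNA count per library ran from 136692 to 242935 in body and from 52792 to 275974 in hemolymph. Old hemolymph libraries were shallower (mean 82120 ± 27214, n = 8) than old body libraries (165340 ± 29776, n = 8), with no overlap between the groups (exact permutation p = 0.000155, adjusted p = 0.000775). At equal depth, 141 ± 6.89 microRNAs were detected in old hemolymph and 161 ± 3.11 in old body, again without overlap (adjusted p = 0.000775). The same measure gave 139 ± 6.46 in young hemolymph and 161 ± 2.62 in young body (exact permutation p = 0.0286, the smallest possible with 4 against 4, adjusted p = 0.0572).

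Each compartment had its own leading microRNA. In all 12 body libraries this was miR-956-3p (hairpin at chromosome 3L, 11773731 to 11773878, minus strand, with no annotated host gene on its strand), at 22.3% ± 1.65 of counts in old body (SD, n = 8) and 21.5% ± 3.44 in young body (n = 4). In old hemolymph miR-8-3p, a regulator of fat body growth and insulin signalling encoded at 2R, 16831432 to 16831518 (plus strand, in an exon of a noncoding RNA), took 33.0% ± 5.13 of counts (n = 8). Young hemolymph held 21.9% ± 7.15 miR-8-3p and 16.8% ± 1.96 miR-276a-3p (n = 4), a microRNA known from the nervous system, and miR-276a-3p led in young hemolymph libraries 1 and 2. Among 206 hairpins with both arms listed, minor arms took 5.09% ± 0.427 of counts in old hemolymph and 2.60% ± 0.172 in old body. The groups did not overlap (exact permutation p = 0.000155, adjusted p = 0.000775). The minor arm was the arm with fewer counts over all 24 libraries. Body libraries held more counts on average, so that definition may itself lower the minor arm share in body.

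The first question was which microRNAs differ between hemolymph and body in young flies. The body's leading microRNA, miR-956-3p, lay at 5045 ± 2975 CPM in young hemolymph, a log2 fold change of -5.32 ± 0.50 from young body (SE, adjusted p = 1.1e-09). The homeotic cluster microRNA miR-10-5p (-5.45 ± 0.43), the muscle microRNAs miR-133-3p (-5.66 ± 0.47) and miR-1-3p (-2.92 ± 0.46), and miR-958-3p (-7.37 ± 0.58, 35.4 ± 16.9 CPM in hemolymph against 5941 ± 2761 in body) were also far lower. Higher in hemolymph were miR-980-3p (4.39 ± 0.44), miR-184-5p (3.63 ± 0.38), miR-929-5p (3.06 ± 0.39), miR-284-5p (2.46 ± 0.23) and bantam-5p (2.34 ± 0.29). So were the abundant miR-8-3p (1.52 ± 0.23), miR-276a-3p (1.59 ± 0.27), miR-11-3p (1.40 ± 0.17) and miR-14-3p (1.40 ± 0.27). Of 124 microRNAs tested with edgeR's quasi-likelihood test, 41 were higher and 50 lower in hemolymph. No read of miR-124-3p, miR-314-3p, miR-932-5p or miR-990-5p was counted in any young hemolymph library. Taken against a floor of 3 counts over the group, they were at least 48.9-fold, 54.9-fold, 65.1-fold and 48.9-fold lower than in body.

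By list, 9 of the 12 tested head and nervous system microRNAs were lower in young hemolymph and 3 were higher (the same counts adjusted over the list alone). The lower ones included miR-987-5p (-6.71 ± 0.64), miR-210-3p (-5.72 ± 0.46), miR-1000-5p (-5.67 ± 0.58) and miR-957-3p (-5.45 ± 0.45). The higher ones were miR-929-5p, miR-276a-3p and miR-190-5p (1.47 ± 0.23), and camera, which sets a list against the other microRNAs, did not call it (adjusted p = 0.184). The list's share of counts, which weighs members by abundance, was higher in young hemolymph (17.1% ± 1.86) than in young body (7.22% ± 1.93). These shares did not overlap (exact permutation p = 0.0286, adjusted p = 0.0572), and most of each was miR-276a-3p, at 16.8% and 5.63%. By fry, which tests whether a list moves on balance one way and not against other microRNAs, all 9 tested lists passed in young flies, 3 up and 6 down. The smallest adjusted p-values by fry were 1.4e-06 for muscle, 2.37e-06 for ovary and 2.78e-06 for head and nervous system microRNAs, all down. In the let-7 complex, a single transcript for developmental timing, let-7-5p (1.34 ± 0.31) and miR-125-5p (1.55 ± 0.39) were higher, and miR-100-5p was at 0.82 ± 0.60 (2 of 3 also adjusted over the list alone, camera adjusted p = 0.413). Of the 6 aging and lifespan microRNAs 3 were higher and none lower, namely the former pair and miR-14-3p (3 adjusted over the list alone, adjusted p = 0.413). Upper-quartile scaling gave 5 higher and 0 lower in that list, and RLE scaling 3 higher and 1 lower. Of the 4 muscle microRNAs 2 were lower and miR-9a-5p was higher (1.68 ± 0.44), with the same counts adjusted over the list alone (adjusted p = 0.413). Among 11 gut, fat body and metabolism microRNAs 4 were higher, including miR-8-3p, miR-14-3p and miR-33-5p (1.24 ± 0.25), and all 3 products of the mir-281 hairpins were lower, with miR-281-1-5p at -2.89 ± 0.22 (4 and 3 adjusted over the list alone, adjusted p = 0.965). The median of that list was 0.27 and its mean -0.27, fry pointed down (adjusted p = 0.0155), and under RLE scaling the median was -0.12 with 4 higher and 5 lower. Under upper-quartile scaling the median was 0.93 with 7 higher and 3 lower. Of the 11 tested immune and hemocyte microRNAs 3 were higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.662), and under RLE scaling 2 were higher and 8 lower. Among the higher, bantam-3p (0.56 ± 0.23) was lost without old body library 1, 2, 3, 4, 6, 7 or 8, young body library 3 or 4, or old hemolymph library 4 (0.26 to 0.39). Old libraries are in that fit and not in the contrast. The tested microRNAs shifted by the same median of -0.232 without old body library 2, 3, 4, 6, 7 or 8. There bantam-3p stood at 0.3812 each time, which points to the shared scaling and not to any 1 of those libraries. In the miR-2 family, whose shared seed targets pro-apoptotic genes, 3 of 6 were higher and miR-13b-3p was lower (-0.88 ± 0.23), as adjusted over the list alone (adjusted p = 0.413), and under RLE scaling 1 was higher and 2 lower. Without young libraries 1 and 2, miR-125-5p stood at -0.19 and miR-100-5p at -2.30 (libraries left out after seeing the data). With the replicate block miR-34-5p, miR-92b-3p, miR-263a-5p and miR-311-3p were also lower (adjusted p = 0.00887, 0.000512, 0.0406 and 0.000512). Under RLE scaling the tested microRNAs shifted by a median of -0.48 and under upper-quartile scaling by 0.61, with splits of 36 higher to 60 lower and 55 to 45.

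**Figure D1:**
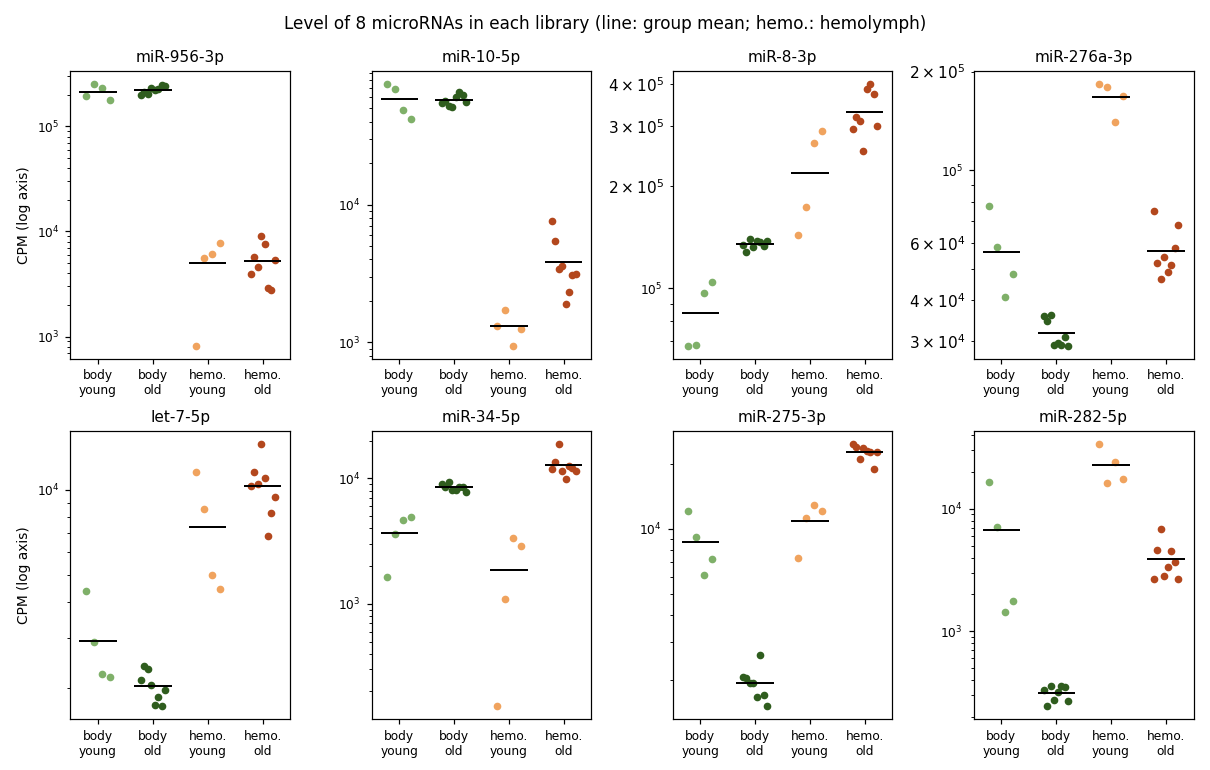
Level of 8 microRNAs in each library, in CPM on log axes, with 1 point per library and a line at the group mean (young n = 4, old n = 8 per compartment). miR-956-3p and miR-10-5p sit far lower in hemolymph, miR-275-3p separates old body (1942 CPM on average) from the other groups, and miR-282-5p is lower in old than in young libraries of each compartment.

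In old flies the contrast between hemolymph and body followed mostly the same microRNAs. The body markers miR-956-3p (-5.55 ± 0.35, adjusted p = 7.0e-13), miR-958-3p (-7.88 ± 0.44), miR-210-3p (-6.39 ± 0.33), miR-133-3p (-5.49 ± 0.34) and miR-10-5p (-4.03 ± 0.28) were lower in hemolymph. Both arms of mir-980 (X, 280172 to 280269, minus strand) were higher, miR-980-5p by 6.06 ± 0.46 and miR-980-3p by 4.39 ± 0.31. The metabolic microRNA miR-275-3p, known for a role in mosquito digestion, was higher by 3.44 ± 0.21 (22562 ± 1783 CPM in old hemolymph, 1942 ± 339 in old body), and miR-282-5p was higher by 3.53 ± 0.43. Of 124 tested microRNAs 45 were higher and 57 lower. Of these, 36 higher and 47 lower calls were shared with young flies, where independent lists would share 14.9 and 23.0 (Fisher's exact p = 1.8e-17 and 1.4e-20). The 2 contrasts compare different libraries but come from 1 fit, with shared scaling and dispersion. The extraction kit also differed with the compartment at both ages. As microRNAs are not independent replicates either, these p-values may be too small. The called direction was opposite for miR-317-3p (-0.94 ± 0.38 in young, 0.65 ± 0.26 in old) and miR-2b-3p (0.78 ± 0.20 in young, -0.59 ± 0.14 in old). Without young body library 2 the young value of miR-317-3p was -0.44 and no longer called, and under upper-quartile scaling neither the young call of miR-317-3p nor the old call of miR-2b-3p passed. Under RLE scaling and with DESeq2 the old call of miR-317-3p (0.39 in each) and the young call of miR-2b-3p (0.27 and 0.28) were lost. Neither microRNA was called in opposite directions under these 3 alternatives, in the fit of the 2 compared groups, with old libraries of either code alone, or without young libraries 1 and 2. Nor was miR-2b-3p without a low-count filter, or miR-317-3p without ovary and miR-310 family microRNAs.

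All 3 members of the let-7 complex were higher in old hemolymph, let-7-5p by 2.23 ± 0.23 (10283 ± 2271 CPM against 2019 ± 249), miR-100-5p by 2.23 ± 0.45 and miR-125-5p by 1.63 ± 0.28, with 3 adjusted over the list alone (camera adjusted p = 0.181). Of the head and nervous system list 3 of 12 were higher and 9 lower, again with miR-276a-3p (0.73 ± 0.19), miR-190-5p (1.58 ± 0.16) and miR-929-5p (2.05 ± 0.26) against the other 9 (the same adjusted over the list alone, adjusted p = 0.176). Among aging and lifespan microRNAs 4 of 6 were higher, the let-7 complex and miR-277-3p (0.48 ± 0.21), and 4 adjusted over the list alone (adjusted p = 0.181). The muscle microRNAs miR-1-3p (-3.38 ± 0.37) and miR-133-3p were lower, 2 of 4 also adjusted over the list alone (adjusted p = 0.41). Of the gut, fat body and metabolism list 5 of 11 were higher and 4 lower, the latter being miR-263a-5p (-1.49 ± 0.33) and the mir-281 products (5 and 4 adjusted over the list alone, adjusted p = 0.624). Immune and hemocyte microRNAs gave 3 higher and 6 lower of 11 (the same adjusted over the list alone, adjusted p = 0.886), and the miR-2 family 1 higher and 4 lower of 6 (the same adjusted over the list alone, adjusted p = 0.834). Yet the immune list took 51.1% ± 4.54 of old hemolymph and 29.0% ± 0.823 of old body counts. The miR-2 family took 3.45% ± 0.360 and 2.70% ± 0.133. Neither list's shares overlapped (exact permutation p = 0.000155, adjusted p = 0.000886 for each). By fry 8 of 9 lists passed, 2 up and 6 down, with adjusted p = 6.55e-07 for aging and lifespan and 1.37e-06 for the let-7 complex (up), and 1.82e-10 for muscle (down). Upper-quartile scaling moved the tested microRNAs by a median of 0.48 and RLE by -0.27. The call of miR-277-3p was lost under RLE scaling, without old body library 5 (0.42) and without old hemolymph library 3 (0.29). With the replicate block it was lost too (0.40, adjusted p = 0.0836), which left 3 of 6 aging and lifespan microRNAs higher.

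Ovary microRNAs were present in these libraries, which are labelled male. In old body miR-318-3p, a microRNA of the ovary's follicle cells, took 2.07% ± 0.475 of counts (n = 8), and in young body it was at 64.0, 6660, 68137 and 54850 CPM in libraries 1 to 4. The ovary microRNA miR-989-3p lay at 3919 ± 592 CPM in old body and 3880 ± 1219 CPM in young body. Of the ovary and early embryo list 3 of 8 members could be tested between compartments, and miR-318-3p (-5.09 ± 1.64 in young, -3.21 ± 1.05 in old) and miR-989-3p (-8.90 ± 0.83 and -5.15 ± 0.45) were lower in hemolymph, 2 adjusted over the list alone at each age (camera adjusted p = 0.413 and 0.594). The old value of miR-318-3p was -5.29 without old hemolymph library 4, and with O-coded old libraries only it was -2.21 and not called (adjusted p = 0.193). With R-coded old libraries only it was -6.65. The miR-310 and miR-92 seed family was likewise lower in hemolymph for 4 of 6 members in young flies and 5 of 6 in old flies, as adjusted over the list alone (adjusted p = 0.413 and 0.624). In old flies miR-312-3p (-1.51 ± 0.63) was no longer called without old hemolymph library 3, 5, 6 or 7 (-1.44 to -1.34). None of the 20 testis cluster microRNAs passed the count filter in any comparison, and the list took 0.0182% ± 0.00275 of counts in old body and 0.0103% ± 0.00290 in young body.

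**Figure D2:**
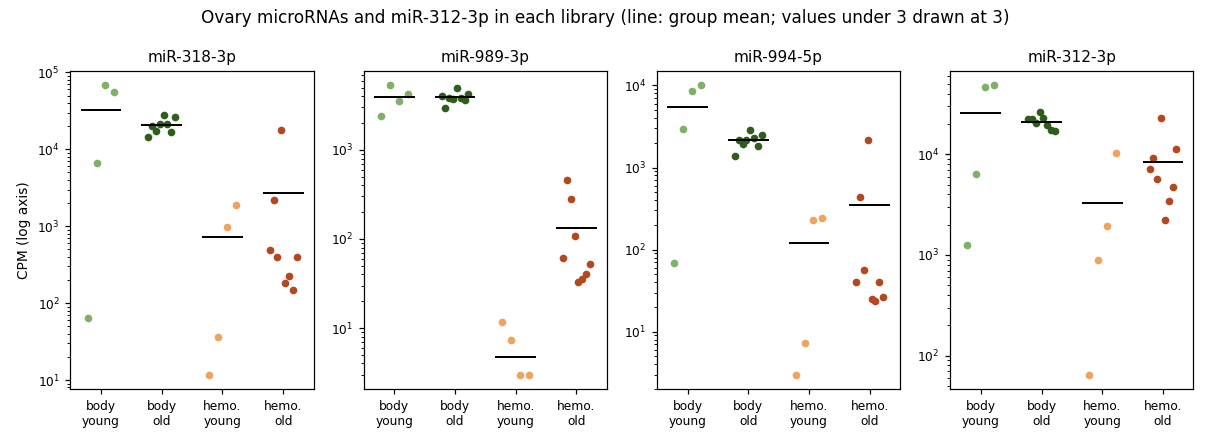
Levels of miR-318-3p, miR-989-3p, miR-994-5p and miR-312-3p in each library, in CPM on log axes, with 1 point per library, a line at the group mean and values under 3 drawn at 3. Young body library 1 lies at 64.0 CPM of miR-318-3p where the old body libraries lie between 14315 and 27895, and old hemolymph library 4 reaches 17907.

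The second question was how the body's microRNAs change from 2 to 25 days. The clearest fall was of miR-275-3p (2L, 7425795 to 7425892, plus strand, in an exon of a noncoding RNA), from 8679 ± 2634 to 1942 ± 339 CPM (log2 fold change -2.25 ± 0.21, adjusted p = 1.2e-05). miR-282-5p fell by 4.59 on the log2 scale (SE 0.55, adjusted p = 5.9e-05), and miR-277-3p, which acts in amino acid metabolism and lifespan, fell from 19420 ± 4359 to 8391 ± 977 CPM (-1.28 ± 0.16, adjusted p = 7.7e-05). The neighbouring miR-34-5p, known for protection of the aging brain, rose from 3703 ± 1496 to 8478 ± 546 CPM (1.19 ± 0.20, adjusted p = 0.00042). Both hairpins lie in exons of 1 noncoding RNA on 3R, mir-277 at 10100022 to 10100121 and mir-34 at 10100936 to 10101034. Other rises were of miR-8-3p (0.66 ± 0.10), miR-33-5p in an intron of SREBP (1.17 ± 0.21), miR-284-5p (1.23 ± 0.20), miR-308-3p (1.62 ± 0.26) and miR-929-5p (1.13 ± 0.23). Other falls were of miR-31a-5p (-1.67 ± 0.31), miR-990-5p (-2.09 ± 0.33) and miR-981-3p (-1.91 ± 0.37). The body's leading miR-956-3p was at -0.01 ± 0.15 and miR-10-5p at -0.12 ± 0.20. Of 115 microRNAs tested 22 rose and 34 fell. The young body libraries spread more than the old ones, and limma with sample weights kept 33 of these 56 calls.

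Of 12 head and nervous system microRNAs 8 fell with age in body and 2 rose, with miR-276a-3p (-0.91 ± 0.19), miR-276b-3p (-1.04 ± 0.17), miR-315-5p (-1.50 ± 0.33) and miR-987-5p (-1.41 ± 0.29) among the falls. miR-210-3p (0.94 ± 0.17) was among the rises (8 and 2 adjusted over the list alone, camera adjusted p = 0.365). The list's share of body counts was 7.22% ± 1.93 in young and 4.25% ± 0.355 in old libraries, without overlap (exact permutation p = 0.00404, adjusted p = 0.0115). Most of that fall was of miR-276a-3p, from 5.63% ± 1.60 to 3.18% ± 0.313, and the other members together went from 1.59% ± 0.337 to 1.07% ± 0.0945. Of 11 gut, fat body and metabolism microRNAs 7 rose and 2 fell, as adjusted over the list alone (camera adjusted p = 0.455), though under upper-quartile scaling 2 rose and 2 fell. Of the 7, miR-281-2-5p (1.05 ± 0.35) was lost without old body library 1, 2, 4, 5, 6 or 8 or young body library 1 or 2 (0.71 to 0.97), and miR-263a-5p (0.34 ± 0.12) without any of 11 libraries, all but young body library 3 (0.19 to 0.35). The list's share was 21.0% ± 3.40 in young and 29.2% ± 1.09 in old body, without overlap (exact permutation p = 0.00404, adjusted p = 0.0115), of which miR-8-3p went from 8.42% ± 1.92 to 13.5% ± 0.395. Of the aging and lifespan list miR-34-5p and miR-14-3p (0.52 ± 0.20) rose and miR-277-3p and let-7-5p (-0.63 ± 0.22) fell, 2 and 3 adjusted over the list alone (adjusted p = 0.843). The call of miR-14-3p was lost without old body library 1, 3, 4, 6 or 8 or young body library 4 (0.36 to 0.49), and that of let-7-5p without old body library 7 (-0.59) or young body library 1 (-0.27) or 2 (-0.52). let-7-5p was the 1 of 3 let-7 complex members to fall, also adjusted over the list alone (adjusted p = 0.498), and miR-1-3p (-1.44 ± 0.26) the 1 of 4 muscle microRNAs, also adjusted over the list alone (adjusted p = 0.498). The immune and hemocyte list gave 2 rises and 3 falls of 11, and the miR-2 family 2 rises and 1 fall of 7, each the same adjusted over the list alone (adjusted p = 0.455 for both). Among the immune falls, bantam-3p (-0.46 ± 0.18) was lost without old body library 2, 3 or 7 or young body library 1 or 2 (-0.48 to -0.26). The immune list had a median of -0.18 and a mean of 0.15. None of 3 ovary microRNAs and none of 6 miR-310 and miR-92 family members passed the test, over all tested or adjusted over the list alone (adjusted p = 0.901 and 0.365). The ovary list had a median of -0.56 where camera pointed up. By fry 3 of 9 lists passed, muscle down and the gut and immune lists up (adjusted p = 0.0369 for each). Upper-quartile scaling shifted the tested microRNAs by a median of -0.10 with 13 rises and 35 falls, and RLE by 0.11. Without young libraries 1 and 2 the counts were 35 rises and 30 falls and miR-10-5p rose (0.40), and without old body library 1 there were 14 rises. With miR-310 family and ovary microRNAs left out there were 30 rises and 22 falls, and limma called 21 and 14.

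The third question was how circulating microRNAs change with age. In hemolymph miR-34-5p rose from 1871 ± 1503 to 12741 ± 2666 CPM (log2 fold change 2.60 ± 0.57, adjusted p = 0.0022), and miR-317-3p, from the same region of 3R (10091126 to 10091217), rose from 36277 ± 21215 to 105300 ± 7102 CPM (1.34 ± 0.36, adjusted p = 0.0078). The 3 products of the mir-281 hairpins rose together, miR-281-1-5p by 1.97 ± 0.20, miR-281-3p by 1.52 ± 0.29 and miR-281-2-5p by 1.42 ± 0.24. Rises were also found for miR-957-3p (2.14 ± 0.45), miR-12-5p (1.38 ± 0.26), miR-10-5p (1.27 ± 0.35), miR-33-5p (1.11 ± 0.25) and miR-275-3p (0.83 ± 0.16). miR-276a-3p fell from 167590 ± 19586 to 56688 ± 9902 CPM (-1.80 ± 0.15, adjusted p = 2.2e-06) and bantam-3p, a growth and survival microRNA, from 86639 ± 14533 to 41163 ± 2813 CPM (-1.32 ± 0.13, adjusted p = 5.6e-06). miR-277-5p (-3.16 ± 0.52), miR-282-5p (-2.79 ± 0.29), miR-2a-3p (-2.41 ± 0.29), miR-9a-5p (-2.33 ± 0.32), miR-1-3p (-1.94 ± 0.48) and miR-31a-5p (-1.74 ± 0.24) also fell. Of 86 microRNAs tested 16 rose and 24 fell, and limma with sample weights kept 38 of these 40 calls.

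Of 11 gut, fat body and metabolism microRNAs 5 rose with age in hemolymph, namely miR-275-3p, miR-33-5p and the mir-281 products, and miR-14-3p (-0.59 ± 0.20) and miR-277-3p (-1.09 ± 0.28) fell, as adjusted over the list alone (camera adjusted p = 0.13). The gut list's share was 37.9% ± 4.21 in young and 49.8% ± 3.99 in old hemolymph, without overlap (exact permutation p = 0.00404, adjusted p = 0.0115). Most of that rise was of miR-8-3p, from 21.9% ± 7.15 to 33.0% ± 5.13. Both muscle microRNAs that passed, miR-1-3p and miR-9a-5p, fell among 3 tested (2 adjusted over the list alone, adjusted p = 0.333). Of 5 tested head and nervous system microRNAs miR-276a-3p and miR-276b-3p (-1.49 ± 0.23) fell and miR-957-3p rose, as adjusted over the list alone (adjusted p = 0.333). That list's share was 17.1% ± 1.86 of young and 6.0% ± 0.988 of old hemolymph counts, without overlap (exact permutation p = 0.00404, adjusted p = 0.0115). That fall was of miR-276a-3p alone, from 16.8% ± 1.96 to 5.67% ± 0.990, as the other members together took 0.308% ± 0.105 and 0.328% ± 0.0405. In the aging and lifespan list miR-34-5p rose, and miR-277-3p and miR-14-3p fell, of 6 (1 and 2 adjusted over the list alone, adjusted p = 0.605). The call of miR-14-3p was lost without old hemolymph library 6 (-0.47) or young hemolymph library 1 (-0.45), 2 (-0.31) or 3 (-0.39). The let-7 complex gave no call in 3 tested, over all or adjusted over the list alone (let-7-5p 0.19 ± 0.27, adjusted p = 0.522 for the list). The immune and hemocyte list gave 2 rises and 1 fall of 8 and the miR-2 family no rise and 2 falls of 5, the same adjusted over the list alone (adjusted p = 0.302 and 0.283). The immune list's share went from 35.6% ± 8.10 to 51.1% ± 4.54, without overlap (exact permutation p = 0.00404, adjusted p = 0.0115). None of 5 miR-310 and miR-92 family members passed, over all tested or adjusted over the list alone (adjusted p = 0.283), and of the ovary list miR-318-3p alone was tested (1.64 ± 1.51). Its old level is dominated by old hemolymph library 4, at 17907 CPM where the next was at 2178. By fry 5 of 8 lists passed, the gut (adjusted p = 1.57e-06) and immune (0.00888) lists up and the muscle (0.00056), head and miR-2 (0.000614 for both) lists down. Without young hemolymph library 2 the falls numbered 13 and miR-1-3p (-1.38) and miR-277-3p (-0.83) were no longer called, nor was miR-277-3p without young hemolymph library 3 (-0.64), and without young libraries 1 and 2 miR-125-5p rose (1.32). Scaling by library size alone shifted the tested microRNAs by a median of 0.24 and gave 20 rises and 19 falls, and upper-quartile scaling shifted them by 0.21.

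Of 81 microRNAs tested for age in both compartments, 8 rose in both and 14 fell in both, where independent lists would share 3.52 and 6.52. The young libraries of the compartments were taken as paired, so independence may not hold for these lists. miR-34-5p, miR-33-5p and the mir-281 products rose in each, and miR-282-5p, miR-276a-3p, miR-31a-5p, miR-277-3p and miR-1-3p fell in each. The fold changes correlated across microRNAs with r = 0.541, though microRNAs are not independent replicates and the pairing may add to it. A further 3 microRNAs rose in body and fell in hemolymph, and 2 fell in body and rose in hemolymph.

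**Figure D3:**
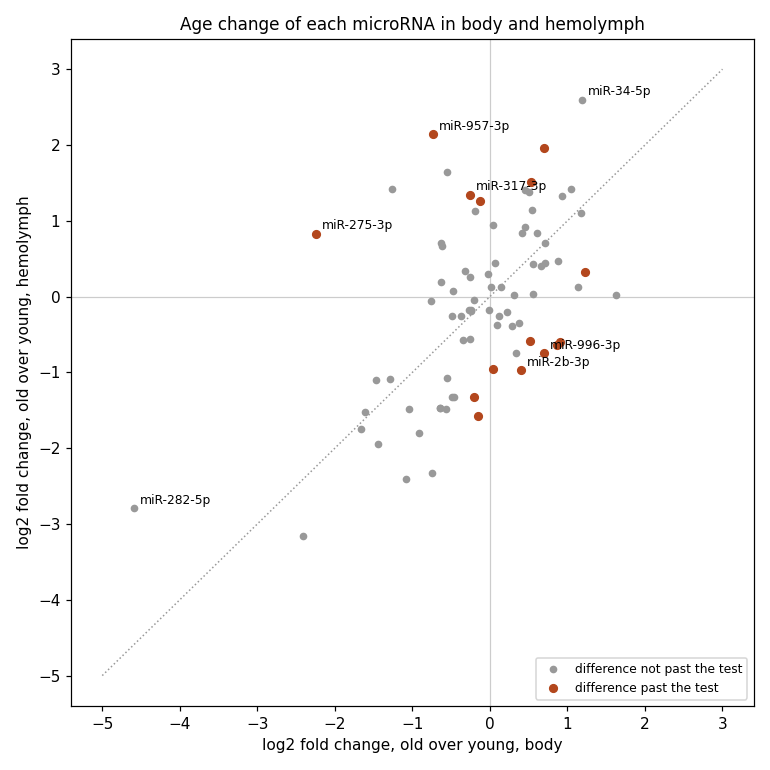
Age change of 81 microRNAs as log2 fold change (old over young) in body on the horizontal axis and in hemolymph on the vertical axis, with a dotted line of equal change. Coloured points mark the 15 microRNAs whose difference between compartments passed the test, with miR-275-3p at -2.25 in body and 0.83 in hemolymph.

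The title of the series asks whether circulating microRNAs accumulate relative to tissue microRNAs with age. Amounts are not measured here, so a general rise in circulating microRNA would not show. The difference between the age changes (hemolymph minus body) compares levels relative to the bulk of the microRNAs in each library. miR-275-3p fell in body and rose in hemolymph, with a difference of 3.10 ± 0.34 on the log2 scale (adjusted p = 2.9e-07). miR-957-3p likewise fell in body (-0.73 ± 0.13) and rose in hemolymph, from 103 ± 44.3 to 522 ± 245 CPM, with a difference of 2.87 ± 0.48 (adjusted p = 0.00014). miR-281-1-5p, from a hairpin at 2R (12170373 to 12170462, minus strand, in an intron of Oda), gained in hemolymph relative to body by 1.22 ± 0.26 (adjusted p = 0.0018), as did miR-317-3p (1.59 ± 0.46, adjusted p = 0.021) and miR-10-5p (1.43 ± 0.44, adjusted p = 0.026). The value of miR-989-3p was higher still (3.75 ± 0.93, adjusted p = 0.0078) but rested on 4.76 ± 5.79 CPM in young and 133 ± 154 CPM in old hemolymph. In the opposite direction, miR-996-3p rose in body (0.69 ± 0.11) and fell in hemolymph (-0.75 ± 0.20), a difference of -1.43 ± 0.23 (adjusted p = 0.00012), and miR-2b-3p rose in body (0.40 ± 0.12, lost without old body library 1, at 0.25, or 4, at 0.32) and fell in hemolymph (-0.97 ± 0.20), a difference of -1.37 ± 0.24 (adjusted p = 0.000225). Of 124 microRNAs tested 8 gained and 10 lost in hemolymph relative to body. That balance depends on filter and scaling, with 21 gains and 2 losses at a mean of at least 100 CPM and 8 and 19 under upper-quartile scaling. The call of miR-317-3p was lost without young body library 2 (1.09) and that of miR-10-5p without young body library 1 (1.16) or 2 (1.25).

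The miR-2 family was the 1 list called by camera in any comparison without the replicate block, lower in hemolymph relative to body (adjusted p = 0.0053, and adjusted p = 0.22 with an estimated correlation). With the replicate block these were 0.00122 and 0.0215, and under RLE scaling 0.00664 and 0.0251. Under upper-quartile scaling and by library size alone the list passed at the preset correlation (0.0042 and 0.0106) and not at the estimated one (0.106 and 0.126). By fry the family passed as well (down, adjusted p = 0.000216), as did the gut list (up, adjusted p = 0.0249). Of the miR-2 family, miR-2b-3p and miR-2c-3p (-1.40 ± 0.44) passed of 6 tested, and 5 were lower adjusted over the list alone. Under upper-quartile scaling 5 passed, and 3 passed under RLE scaling, by library size alone and with the replicate block. miR-2c-3p was lost without old body library 2, 3, 4, 6 or 7 or young body library 3 or 4 (-1.18 to -1.01). In the gut, fat body and metabolism list 3 of 11 gained and miR-14-3p lost (-1.07 ± 0.33), as adjusted over the list alone (adjusted p = 0.296). Of these miR-281-3p (0.96 ± 0.31) was no longer called without young body library 2 or old hemolymph library 1, 3 or 8 (0.87 to 0.98), and miR-14-3p without old body library 1, 2, 3, 4, 6, 7 or 8, young body library 3 or 4, or old hemolymph library 4 (-0.82 to -0.72). miR-957-3p alone passed in the head and nervous system list of 12, also adjusted over the list alone (adjusted p = 0.939, where the mean was 0.29 and camera pointed down). miR-14-3p alone passed in the aging and lifespan list of 6, also adjusted over the list alone (adjusted p = 0.477). No member of the let-7 complex passed, with let-7-5p at 0.89 ± 0.38 (list adjusted p = 0.296, and 0.0449 with the replicate block, or adjusted p = 0.197 there with an estimated correlation), nor any adjusted over the list alone. RLE scaling and library size alone each called 1 of the 3 higher. With the replicate block let-7-5p (0.82, adjusted p = 0.0149), miR-100-5p (2.23, adjusted p = 0.00993) and miR-34-5p (1.84, adjusted p = 0.0198) gained. miR-9a-5p (-1.65), miR-2a-3p (-1.47), miR-276a-3p (-1.01) and bantam-3p (-0.92) lost there, though they did not pass without the block. Of the muscle list none of 4 passed and 1 was lower adjusted over the list alone (adjusted p = 0.556). The immune and hemocyte list gave 1 gain of 11 and the ovary list 1 of 3, the same adjusted over the list alone (adjusted p = 0.485 and 0.477). None of 6 miR-310 and miR-92 family members passed, also adjusted over the list alone (adjusted p = 0.485). Without young body library 2 there were 5 gains, and without old body library 6, 7 or 8, young body library 3 or 4, old hemolymph library 4 or young hemolymph library 1 or 4 there were 13 to 18. The losses numbered 2 to 4 without old body library 1, 2, 3, 4, 6, 7 or 8 or young body library 3 or 4, 16 without old body library 5 and 17 without young body library 1. Leaving out any library of that first set shifted the tested microRNAs by a median of 0.246 to 0.321. That step in the scaling is common to them, so the calls lost there do not single out a library. RLE scaling shifted the tested microRNAs by a median of 0.20 (15 gains, 13 losses), library size alone by 0.17 (13 and 11) and upper-quartile scaling by -0.13 (8 and 19). miR-275-3p and miR-957-3p stayed called in all 40 alternatives.

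The old libraries carrying R and O codes were compared as a check. In body edgeR's quasi-likelihood test called 0 of 115 microRNAs (3 at an unadjusted p below 0.05), DESeq2 called 0 and limma 4. In hemolymph 1 of 86 was called, miR-998-5p, a microRNA chosen after its values were seen, which was lower in R-coded libraries (-1.52 ± 0.32, adjusted p = 0.038), and 8 had an unadjusted p below 0.05. Of 15 composition measures and list shares, 4 in body and 4 in hemolymph did not overlap between the codes (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.107 over 30 tests chosen after seeing the data). At that floor no measure can pass the adjustment unless most of the 30 separate, so the test cannot show the codes to be alike. A single measure separates by chance with probability 0.0286, so 4 of 15 in each compartment exceed what independent measures would give on average. The measures share microRNAs and are not independent, and a difference between the codes stays possible. The separated measures in body were the shares of the 10 most abundant, the let-7 complex, muscle and the miR-310 and miR-92 family. In hemolymph they were microRNAs detected at equal depth (133 to 140 R-coded, 142 to 155 O-coded) and the testis, ovary and miR-2 shares. The muscle list took 1.42% to 1.54% of R-coded and 1.77% to 1.86% of O-coded body counts, and the miR-2 family 2.87% to 3.32% and 3.55% to 3.88% of hemolymph counts. miR-998-5p was no longer called without old hemolymph library 1, 3, 5, 6, 7 or 8 or young hemolymph library 2 or 3 (-1.62 to -1.07). It was not called without a low-count filter (-1.30), under upper-quartile scaling (-1.41) or with robust dispersion (-1.52) either. The count of calls was 0 without those libraries, except that another microRNA was called without old hemolymph library 3, and 3 without old hemolymph library 2 or young hemolymph library 1 or 4.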

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

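The explanations weighed below were tested with bounds set after the result was seen, except body RNA carried into old hemolymph library 4 and the young body libraries without ovary microRNAs. A library was picked out where its gap to the nearest other library of its group was wide against the group's range, which chance does in about 1 in 20 groups. That happened in 8 of 120 groups, where 6.0 are expected by chance.

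Ovary microRNAs were found in body libraries labelled male, and old hemolymph library 4 stood apart in the same microRNAs. In 12 of 12 body libraries the ovary and early embryo list took at least 10 times the share of the testis clusters (smallest ratio 33.6). That ratio restates the observation that prompted it and adds no support, so ovary RNA may be present but was not tested apart from it. The male label of the body libraries is thus in doubt. The ovary list's share ran from 0.251% to 7.25% in young and from 1.84% to 3.30% in old body. Whether ovary content moves other microRNAs in the age comparison of body was not tested. In body 2 of 8 members of that list, miR-318-3p and miR-989-3p, and 0 of 20 testis members reached a mean of 100 CPM. Reads of other sequences assigned to miR-318-3p are argued against by the neighbouring miR-994-5p, at 100 CPM or more in 11 of those libraries. In old hemolymph library 4, miR-318-3p was at 17907 CPM (next 2178), miR-994-5p at 2182 CPM (next 436), the ovary list at 1.80% (next 0.269%), the miR-310 and miR-92 list at 4.98% (next 2.41%) and the muscle list at 2.24% (next 1.39%). Carry-over of body RNA stays open, since the other 49 microRNAs rose there by a median of 3.8% of their body level (upper quartile 22.8%) against 85.6% for 8 ovary and miR-310 members (lower quartile 12.3%), and among abundant body microRNAs miR-263a-5p rose by 29.4%, miR-956-3p by 2.02% and miR-10-5p by 0.799%, and no biological explanation was tested, as sex is no group of the design.

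The young body libraries differed more among themselves than the old ones, with a lowest pairwise r across microRNAs of 0.795 against 0.988. Shallow sequencing is argued against by the lowest total of a young body library, 180182, above the old median of 159236. Without the ovary and miR-310 family microRNAs the lowest r was 0.919 in young against 0.99 in old body (105 microRNAs, pseudocount 10 CPM). A differing share of these microRNAs alone is thus argued against as the whole cause. Other microRNAs were kept whether or not ovary tissue holds them, so a differing amount of ovary tissue was not tested and stays open. The deviations of young body libraries 1 to 4 from their mean correlated with the age change in hemolymph at r = -0.48, -0.106, 0.379 and 0.375 across 74 microRNAs, which are not independent replicates, where old body libraries lay between -0.284 and 0.128. Deviations from a group mean cancel out across its libraries, so correlations of both signs are in part built in. The young body libraries may differ in their position along the age change, a hypothesis found and tested on the same data. The pairing of young body with young hemolymph libraries also leaves it open.

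miR-275-3p differed in its age change between hemolymph and body by 3.10 on the log2 scale. The scaling of the libraries is argued against by a lowest value of 2.93 under 3 other scalings. Single young libraries are argued against by values of 2.54 without young libraries 1 and 2 and 3.65 without 3 and 4. An equal change of the whole hairpin transcript is argued against by the other arm, miR-275-5p, at 0.51, which lay 5.3 standard errors from miR-275-3p. A change specific to this arm in old flies is a hypothesis that these tests leave open, and a difference between the compartments with age was not tested in other samples.

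Old body library 3 had the highest total of its group, 230282 (next 177723). Old body library 5 had the lowest share of the miR-2 family in its group, 2.42% (next 2.64%). In old hemolymph library 3 miR-282-5p was at 6838 CPM (next 4610). The age change in hemolymph minus that in body differed from 0 by the test of the difference for 17 microRNAs besides miR-275-3p. The gains were of miR-4919-3p (4.94, a value that rests on no read in young hemolymph), miR-989-3p (3.75), miR-957-3p (2.87), miR-317-3p (1.59), miR-10-5p (1.43), miR-281-1-5p (1.22) and miR-281-3p (0.96). The losses were of miR-10-3p (-1.52), miR-316-5p (-1.48), miR-9c-5p (-1.46), miR-996-3p (-1.43), miR-2c-3p (-1.40), miR-2b-3p (-1.37), miR-9b-5p (-1.12), miR-14-3p (-1.07), miR-279-3p (-0.99) and miR-284-5p (-0.94). Without old body library 1, 2, 3, 4, 6, 7 or 8 or young body library 4, miR-10-3p (-1.25 to -1.06), miR-316-5p (-1.29 to -1.09), miR-9c-5p (-1.23 to -0.87), miR-9b-5p (-0.96 to -0.71), miR-279-3p (-0.71 to -0.62) and miR-284-5p (-0.82 to -0.47) were no longer called. Each of these omissions shifted the tested microRNAs by a median of 0.246 to 0.321, a common step in the scaling. The ranges given for these microRNAs take in the further losses, which came without young body library 3 for all of them but miR-9c-5p, old hemolymph library 4 for miR-10-3p, miR-279-3p and miR-284-5p, young hemolymph library 1 for miR-9c-5p, miR-9b-5p and miR-284-5p, and young hemolymph library 2 for miR-316-5p and miR-9b-5p. miR-284-5p was also lost without young body library 2 or young hemolymph library 3 or 4.

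Other splits of the same libraries were refitted to see how often a chance split of them gives as many calls. For young hemolymph against young body the splits that part each of the 4 pairs number 8, too few for a share under 1 in 20 (91 calls, highest other 27, and 93 and 0 with the replicate block), and the highest over all 35 splits, which part fewer pairs, was 36. For old hemolymph against old body 1 of 100 splits, the real one, gave as many calls (102, highest other 76), for age in body 1 of 100 (56, highest other 21), for age in hemolymph 1 of 100 (40, highest other 13) and for the difference of age changes 1 of 100 (18, highest other 9, or 2 where each young pair keeps 1 age), a share under 1 in 20 for these 4. No label says whether libraries are separate flies or pools, so chance between flies is not excluded by splitting libraries. For the R and O codes in body all 35 splits gave 0 calls. In hemolymph 1 of 35, the real one, gave as many (1, highest other 0), also under 1 in 20 but resting on 1 call.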

How the results depend on the processing

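The alternatives that leave out young libraries 1 and 2, young libraries 3 and 4, or the ovary and miR-310 family microRNAs were chosen after seeing the data. The cause was not tested for any change below. Both compartment contrasts kept their counts within 1.5 times under every alternative, with 37 to 45 higher and 49 to 57 lower in young flies and 43 to 48 and 56 to 63 in old flies when single libraries were left out. For age in body the rises numbered 13 under upper-quartile scaling, 9 with O-coded and 12 with R-coded old libraries only, 35 without young libraries 1 and 2, and 14 to 25 without single libraries. The falls numbered 14 with limma, 19 with O-coded and 16 with R-coded libraries, 22 without ovary microRNAs and 25 to 38 without single libraries. For age in hemolymph there were 25 rises without young libraries 3 and 4 and 14 falls with O-coded libraries, and 14 to 22 rises and 13 to 25 falls without single libraries. In the difference of age changes the gains were 15 under RLE, 13 by library size, 21 with a mean of 100 CPM, 20 with summed entries, 19 with DESeq2, 3 with R-coded libraries, 15 without young libraries 1 and 2, 13 without 3 and 4, and 5 to 18 without single libraries. The losses were 19 under upper-quartile scaling, 1 without a filter, 2 with a mean of 100 CPM, 5 with summed and 20 with separate entries, 2 with O-coded and 2 with R-coded libraries, 17 without ovary microRNAs and 2 to 17 without single libraries. For the codes limma called 4 lower in body. In hemolymph the count lower was 2 under RLE, 0 under upper-quartile scaling, 3 by library size, 3 with a mean of 100 CPM, 2 with summed and 2 with separate entries, 4 with DESeq2, 2 with limma, 0 with robust dispersion and 0 to 3 without single libraries.

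The replicate block rests on pairing in the young groups and also pairs the old libraries by number. It gave 40 higher and 53 lower in young flies, 45 and 58 in old flies, and 12 gains and 14 losses in the difference. In old flies 1 of 8 same-numbered pairs had an r above 0.1 (-0.322 to 0.122) and none correlated best with its own number, and between ages 2 of 4 had an r above 0.1 in each compartment and 1 of 4 correlated best with its own number. There the block on libraries 1 to 4 gave 5 rises and 15 falls in body and 10 and 10 in hemolymph. With the block, in old flies miR-277-3p lost its call and miR-92b-3p was called lower (-0.97, adjusted p = 0.00218). Beyond the microRNAs given with it above, the block changed no other call between young compartments or in the difference among the microRNAs named by rule.

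Some directions turned. bantam-3p between old compartments was at 0.22 in the fit of those 2 groups. Without young libraries 1 and 2, miR-125-5p (-0.19) and miR-100-5p (-2.30) turned between young compartments, miR-9a-3p (0.72) and miR-10-5p (0.40) in body, miR-125-5p (1.32) and miR-263a-5p (1.61) in hemolymph, and miR-263a-5p in the difference (1.66). Without young libraries 3 and 4, miR-318-3p (2.52) and miR-312-3p (2.37) turned in body. The gut, fat body and metabolism list pointed down between young compartments by fry (adjusted p = 0.0155). Depth limits microRNAs with no count to a floor of 5.25 CPM over the young and 4.57 CPM over the old hemolymph libraries.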

Other observations

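The microRNA encoded beside mir-275, chosen after its values were seen, passed the age test in 1 of its arms. The hairpin mir-305 lies at 2L, 7425972 to 7426044, on the same strand as mir-275. miR-305-3p rose with age in body (0.42 ± 0.13, adjusted p = 0.020) and in hemolymph (0.83 ± 0.16, adjusted p = 0.00091), and miR-305-5p was at -0.02 ± 0.15 in body and 0.30 ± 0.19 in hemolymph and passed in neither (edgeR's quasi-likelihood test).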
